A study of Mus musculus with 4 samples.

How the data were processed

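Single-cell RNA and surface protein tags were measured with a 10x Genomics droplet kit (version 3) in implant-associated tissue of S. aureus-infected mice, 14 days after infection. Live Ly6G+Ly6C+ cells (Ly6GC positive sort) and Ly6C+Ly6G- cells (Ly6GC negative sort) were collected by flow cytometry. Per the labels, 13627 and 1624 cells were processed, with post-sort viabilities of 89.4% and 79.6%. The deposited matrices held the same numbers of barcodes, 13627 and 1624. The deposited values are raw UMI counts per gene and cell, made with Cell Ranger 7.0.0 per the file headers, while the submitters' processing notes name Cell Ranger 4 and the mm10 genome build. The 2 antibody tags, F4/80 and I-A/I-E, were deposited as counts in the same matrices and were read from there. Cell annotations of the authors were not used here. The features held 32285 genes, of which 25442 had a UMI in either sort and 32158 IDs matched GENCODE vM21 (GRCm38, the mm10 assembly), the source of the coordinates.

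Each sort had 1 RNA library, so no test across samples was possible and no p-value, standard error or test across cells was computed. The design, the gene lists, the markers and the alternatives were fixed before the data were examined, apart from those named as chosen after seeing the data. Cells with fewer than 200 genes or over 10% mitochondrial UMIs were left out, 90 in the positive and 179 in the negative sort. Doublets were called with Scrublet in scanpy 1.11.5 within each sort. It marked 0 of 13537 cells in the positive sort and 5 of 1445 in the negative sort, and the 5 were left out. Both shares are under 0.5%, below what such loadings give, so the caller did not work in either sort and doublets remain among the cells used. Used cells summed to 127283557 UMIs in the positive and 31224673 UMIs in the negative sort. The limit of a count of 0 was taken as 3 counts, which is 0.0236 CPM in the positive and 0.0961 CPM in the negative sort.

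Both sorts were clustered together: counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components and 15 exact neighbours were used. The shared-neighbour graph (Jaccard weights) was split by the Leiden method in python-igraph 0.11.9 at resolution 1.0, with seed 1. Clusters were named from 17 fixed marker lists, with monocyte and macrophage and with T and NK cell markers merged into 15 classes. A marker counted at 50 CPM or more in at least 10% of the cluster's cells. A name needed at least 3 counted markers and 40% of its list, and no more markers of another class than of its own among the top 10 genes by fold. A cluster without any own marker there was also refused a name when its median UMIs lay far under that of its sort. No cell was corrected for free RNA.

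Between sorts, UMIs were summed per gene and expressed as counts scaled to a common total (CPM). The ratio was given with the exact 95% interval of 2 Poisson counts (conditional binomial, scipy 1.17.1). A gene was counted when this interval lay wholly beyond 4-fold and the higher sort had at least 20 CPM. Named genes were fixed by rule: the sort and tag genes, then the 12 largest ratios in each direction at 200 CPM or more without mitochondrial, ribosomal protein and unnamed gene models, and up to 4 members of each list with the highest CPM. Other genes named were taken from the lists to show members that passed. For each of 25 gene lists the median log2 ratio of members at 20 CPM or more was set against 10000 random lists of the same size matched on expression in 20 bins, as a description of these libraries. The lists covered primary granule, secondary granule, tertiary and mature neutrophil genes, G-MDSC-associated genes, suppressive mediators, inflammatory cytokines and chemokines, their receptors, pattern recognition, hypoxia response, glycolysis, oxidative phosphorylation, NADPH oxidase, class II presentation, interferon-stimulated genes, lysosome and phagocytosis, complement, iron handling, granulocyte and monocyte/macrophage transcription factors, osteoclast genes, extracellular matrix and repair, G2/M, S phase, dissociation and stress, and apoptosis.

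Tag-high cells were those assigned to the higher of 2 Gaussian components fitted to log10 (tag UMIs + 1) over both sorts with equal weight per sort. A cell at or below the lower component's mean was never called high, and a cell at or above the higher mean always was. Within the positive sort, summed CPM of tag-high and tag-low cells were compared by the same rule at 2-fold, and the 10 largest ratios per direction at 100 CPM or more were named. Spearman's rho was computed across cells within a sort between a tag and its RNA (Adgre1, or the sum of H2-Ab1, H2-Aa and H2-Eb1). A cell was counted as cycling with at least 2 different G2/M transcripts after thinning to 1000 UMIs. Shares carry exact Clopper-Pearson 95% intervals and sums exact Poisson intervals.

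The steps across genes were tested on simulated counts drawn from the real profiles and totals, with 200 genes changed by known folds. Between the sorts, 50 of 50 genes changed 6-fold and 50 of 50 changed 8-fold were counted among 5858 genes in the step, and 0 of 50 at 2.4-fold or 3-fold. For the F4/80 comparison 50 of 50 genes at 3-fold and 0 of 50 at 1.5-fold were counted among 4519 genes. The I-A/I-E comparison gave the same numbers among 4512 genes. These counts were drawn with the counting error that the intervals assume, without differences between libraries or cells. The simulation thus checks the calculation and says nothing about such differences.

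The alternatives were no cell filter, a stricter filter (500 genes, 5% mitochondrial UMIs), doublets kept, equal weight per cell, median-of-ratios scaling, a denominator without the 20 most abundant genes, floors of 5 and 100 CPM, thinning, other clustering settings, other tag thresholds and other cycling rules. Added after seeing the data were leaving out the highest doublet scores (at 0.8% expected doublets per 1000 cells), leaving out erythroid barcodes (hemoglobin at 1% of UMIs or more), leaving the cluster richest in secondary granule RNA out of the tag comparisons, and neutrophil-like cells of the positive sort against monocyte/macrophage-like cells of the negative sort. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.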

Results

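Leukocytes were taken from tissue around infected joint implants of wild-type mice, 14 days after Staphylococcus aureus was introduced. The series title asks about the fate of granulocytic myeloid-derived suppressor cells (G-MDSCs) in biofilm infection. Cells were sorted by surface Ly6G and Ly6C. The Ly6GC positive sort took cells that carried both markers, the usual gate for granulocytes and G-MDSCs. The Ly6GC negative sort took cells with Ly6C and without Ly6G, the usual gate for monocytes. After sorting, both populations were stained with antibodies to F4/80, a macrophage surface protein, and to I-A/I-E, the mouse MHC class II proteins. Each antibody carried an oligonucleotide tag that was sequenced with the RNA of the same cell. The labels give 1 RNA library per sort, so no difference below has a replicate check and no p-value is given. Intervals are 95% intervals and cover counting error only.

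The Ly6GC positive library held 13627 barcodes and 127481099 RNA UMIs, and the Ly6GC negative library held 1624 barcodes and 31707376 RNA UMIs. After filtering, 13537 cells with a median of 7691 UMIs and 1779 genes remained in the positive sort. In the negative sort 1440 cells remained, with a median of 19672.5 UMIs and 4281 genes. One UMI in the summed profile was worth 0.00786 counts scaled to a common total (CPM) in the positive sort and 0.0320 CPM in the negative sort. The most abundant gene in both was Fth1, the ferritin heavy chain, with 5.49% of the UMIs in the positive sort and 2.14% in the negative sort.

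The first question was which cells each gate had collected. The Ly6GC positive sort was almost wholly neutrophil-like: 13402 of 13537 cells, or 99.003% (95% exact binomial interval 98.8 to 99.2). It also held 125 monocyte/macrophage-like cells (0.923%, 0.769 to 1.10), 8 neutrophil precursor-like cells and 2 T/NK cell-like cells. In the Ly6GC negative sort 1107 of 1440 cells were monocyte/macrophage-like (76.9%, 74.6 to 79.0) and 221 were neutrophil precursor-like (15.3%, 13.5 to 17.3). That sort also held 80 T/NK cell-like cells (5.56%, 4.43 to 6.87), 20 plasmacytoid dendritic cell-like cells (1.39%, 0.850 to 2.14) and 12 neutrophil-like cells (0.833%, 0.431 to 1.45). No plasmacytoid dendritic cell-like cell was found among the 13537 cells of the positive sort, which allows a share of up to 0.0222%. The gates on Ly6G and Ly6C set these shares, so they describe the sorts and not the tissue.

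**Figure D1:**
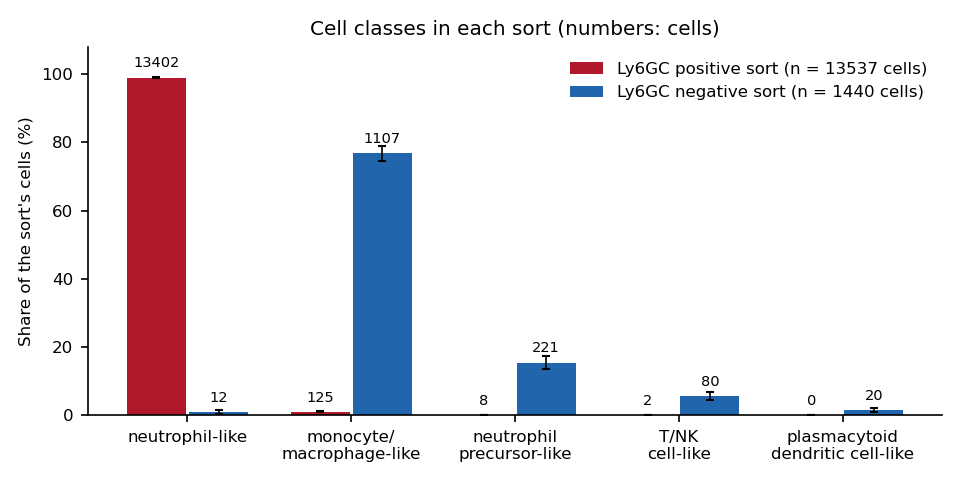
Share of each sort's cells (percent, bars from 0) in 5 cell classes named from fixed marker genes; error bars are exact binomial 95% intervals and the numbers over the bars are cells. Neutrophil-like cells made up 99.003% of the Ly6GC positive sort, and monocyte/macrophage-like cells 76.9% of the Ly6GC negative sort.

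The classes came from 19 clusters of both sorts together, of which 12 were neutrophil-like, 3 neutrophil precursor-like, 2 monocyte/macrophage-like, 1 T/NK cell-like and 1 plasmacytoid dendritic cell-like. With 1 library per sort, a cluster that lies mostly in 1 sort may reflect that library and not a cell type. The doublet caller marked 0 of 13537 cells in the positive sort and 5 of 1445 in the negative sort. Both shares are under the 0.5% set as its lowest credible yield, so it did not work in either sort. A neutrophil-like cluster of 693 cells had a median of 20837 UMIs, and 72.3% of its cells were among the highest doublet scores.

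Marker genes of cell types outside the 5 classes were low in the summed profiles, with erythroid markers highest. Neutrophil markers, 17 genes together, summed to 85128 CPM in the positive sort and 23420 CPM in the negative sort. The combined monocyte and macrophage markers summed to 2444 and 11050 CPM in the same order, and the neutrophil precursor markers to 4.37 and 2404 CPM. The neutrophil sum was thus the larger in the negative sort too, although 12 of its 1440 cells were neutrophil-like. The source of that RNA was not tested. The T and NK cell markers gave 23.4 and 468 CPM, plasmacytoid dendritic cell markers 22.0 and 339 CPM, and conventional dendritic cell markers 45.2 and 78.3 CPM. B and plasma cell markers gave 29.8 and 111 CPM, fibroblast and stromal markers 7.29 and 100.4 CPM, endothelial markers 25.6 and 61.2 CPM, and osteoclast markers 90.8 and 62.1 CPM. Eosinophil markers gave 8.79 and 21.4 CPM, mast cell and basophil markers 0.212 and 1.47 CPM, platelet and megakaryocyte markers 4.42 and 30.7 CPM, and skeletal muscle markers 2.66 and 2.15 CPM. Erythroid markers stood at 318 CPM in the positive sort and 2.40 CPM in the negative sort. Of the hemoglobin UMIs in the positive sort, 99.1% came from 5 barcodes.

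The sorts were then compared gene by gene, to describe what sets granulocytes at the implant apart from the Ly6C-bearing cells beside them. RNA of Ly6g followed its gate. Both gates took cells with surface Ly6C, yet Ly6c2 RNA differed widely. Ly6g (chromosome 15, 75155240 to 75159126, mm10) was at 55.0 CPM in the positive sort and 2.75 CPM in the negative sort, 19.95-fold higher (16.1 to 24.98). Ly6c2 (chromosome 15, 75108158 to 75111970) was at 72.0 and 1118 CPM, 15.5-fold higher in the negative sort (15.2 to 15.9). Ly6c1 was nearly absent, at 0.0550 and 1.25 CPM. The pan-leukocyte gene Ptprc was at 1420 and 975 CPM and the integrin gene Itgam at 440 and 396 CPM. Adgre1, which encodes F4/80 (chromosome 17, 57358691 to 57483527), was at 130 CPM in the positive sort and 123 CPM in the negative sort.

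Among 7009 genes with at least 20 CPM in either sort, 436 had an interval wholly beyond 4-fold in favour of the positive sort and 1718 in favour of the negative sort. These counts describe the 2 libraries and are not a test. The median ratio of 4016 genes at 20 CPM or more in both sorts was −0.23 on the log2 scale, positive over negative, so a typical gene of both sorts stood slightly lower in the positive sort. Counts that used only genes at 100 CPM or more were 241 and 470.

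The 12 largest ratios in favour of the positive sort included known neutrophil genes beside genes of other kinds. Stfa2l1, a stefin-family gene (chromosome 16, 36156811 to 36161953), was at 1109 and 1.02 CPM, 1082-fold higher (767 to 1582). Cstdc4, another cystatin-like gene, was 768-fold higher and Asprv1, a skin-type aspartic protease, 759-fold. Retnlg, which encodes a resistin-like protein of neutrophils (chromosome 16, 48872621 to 48874496), was 404-fold higher (334 to 492). Mmp9, the gelatinase of tertiary granules (chromosome 2, 164940780 to 164955850), was 286-fold higher (200.2 to 424). Myo1d, Csf1, Cxcr2, Mreg, Il1f9, G0s2 and Ankrd33b followed, between 144-fold for Myo1d and 94.5-fold for Ankrd33b. Csf1 encodes the growth factor of macrophages and stood at 498 CPM in the positive sort against 4.32 CPM. Stefin and cystatin-like genes form a family of near-identical copies, so their reads may be split between members.

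The 12 largest ratios in favour of the negative sort included genes of primary granules, of monocytes and of DNA replication. Ctsg, cathepsin G (chromosome 14, 56099881 to 56102574), had 1 UMI in the positive sort and stood at 310 CPM in the negative sort, a ratio of 39512 with an interval from 7090 to 1.56e+06. Elane, neutrophil elastase (chromosome 10, 79886247 to 79888215), was 14175-fold higher (6511 to 38630), Prtn3 1347-fold and Mpo 1148-fold (803 to 1702). Ccr2, the chemokine receptor of inflammatory monocytes (chromosome 9, 124101950 to 124113557), was at 2.498 CPM in the positive and 817 CPM in the negative sort, 327-fold higher in the latter (293 to 366). Ms4a4c, Ms4a6b, Ms4a6c, Pld4 and Ly86 were between 95.7-fold and 151-fold higher. The replication-linked genes Hist1h1b and Pclaf were 155-fold and 129-fold higher.

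**Figure D2:**
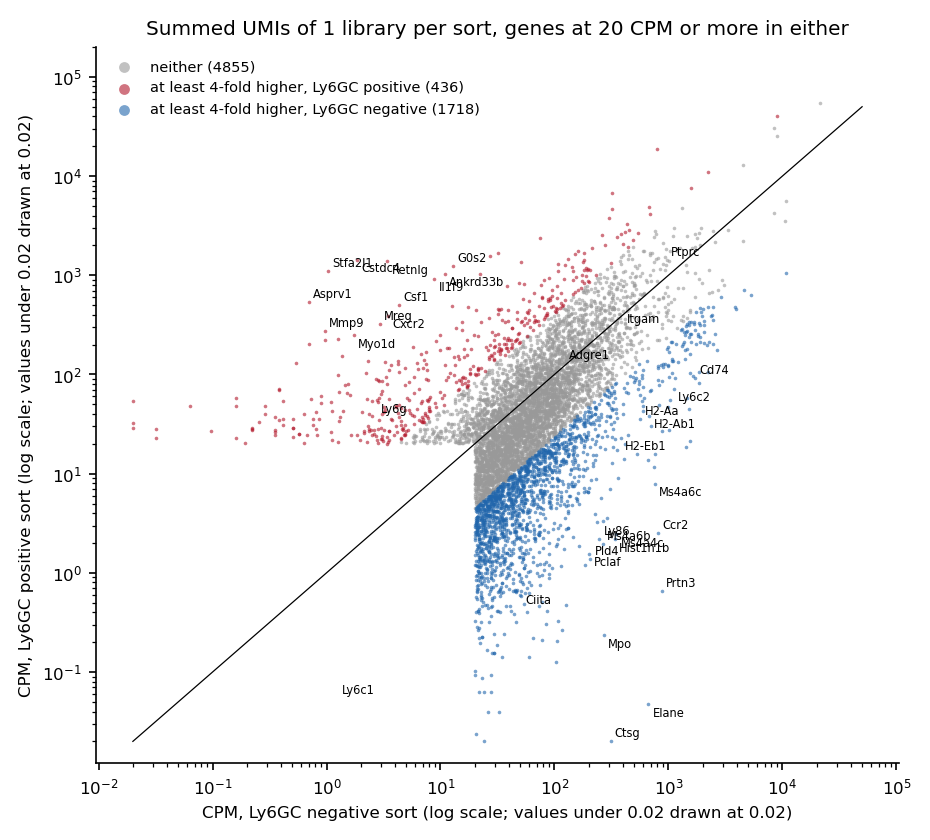
Summed CPM of each gene in the Ly6GC positive sort (vertical, log scale) against the Ly6GC negative sort (horizontal, log scale), genes with at least 20 CPM in either; each point is a gene, and colours mark the 436 and 1718 genes whose interval lies beyond 4-fold. Sort genes and the genes with the largest ratios are named, with Stfa2l1 and Asprv1 at the upper left and Elane and Ctsg at the lower right.

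Primary and tertiary granule genes went opposite ways between the sorts. The negative sort was mostly monocyte/macrophage-like, so these ratios set neutrophils against monocytes as well as against precursors. All 6 measured primary granule genes, which neutrophils transcribe as promyelocytes, were over 4-fold higher in the negative sort (median log2 ratio −10.28, with none of 10000 matched random lists lower). Of 10 tertiary granule and mature neutrophil genes, 9 were over 4-fold higher in the positive sort, among them Hdc (57.7-fold), Retnlg and Clec4d (6.89-fold), and their median of 6.22 lay above all 10000 random lists. Secondary granule genes went both ways. Lcn2 was 5.97-fold higher in the positive sort (4120 against 690 CPM), and Chil3 8.02-fold higher in the negative sort. Camp stood at 894 and 2955 CPM and Ngp at 1065 and 1707 CPM in the positive and negative sorts, and 6 of the 8 members were within the 4-fold bound (median −0.37). When neutrophil-like cells were set against monocyte/macrophage-like cells alone, an alternative chosen after seeing the data, the secondary granule median was 2.97. Of the granulocyte transcription factors, Mxd1 was 10.9-fold higher in the positive sort, 1 was over 4-fold higher in the negative sort and 4 were neither. Cebpb stood at 2960 and 1118 CPM.

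Several of the most abundant inflammatory genes were higher in the granulocyte sort, and others went the opposite way or differed little. Of 19 cytokine and chemokine genes, 9 were over 4-fold higher there, 5 were higher in the negative sort and 5 were neither. Their median log2 ratio of 1.65 lay above all 10000 random lists. Cxcl2, a neutrophil-attracting chemokine (chromosome 5, 90903871 to 90905938), reached 18794 CPM against 795 CPM, 23.7-fold higher (23.4 to 23.9). Ccl3 and Ccl4, which attract monocytes and lymphocytes, were 14.7-fold and 12.7-fold higher. Il1b (chromosome 2, 129364570 to 129371139) was at 7529 and 1568 CPM, 4.8003-fold higher. Pattern recognition genes had a median of 1.88, with 4 of 9 over 4-fold higher in the positive sort and 1 in the negative sort. Nlrp3, the inflammasome sensor, was 10.2-fold higher and the formyl peptide receptor gene Fpr1 21.8-fold. Interferon-stimulated genes had a median of 1.58, with 9 of 19 higher in the positive sort and 1 in the negative sort; Slfn4 was 17.2-fold and Rsad2 11.1-fold higher. Of 12 chemokine and growth factor receptors, 4 were higher in the positive sort, including Il1r2 (46.4-fold) and Csf3r (10.2-fold), and 3 in the negative sort, including Ccr2 (median 0.79).

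Some genes linked to G-MDSCs were higher in the positive sort, and suppressive mediators went both ways. Of 14 G-MDSC-associated genes, 4 were over 4-fold higher in the positive sort (Arg2, Clec4e, Clec4d and Il1b) and 10 were neither. The median of 1.58 lay above 98.99% of random lists. Arg2, Clec4d and Il1b are each in another of the gene lists too. The negative sort was mostly monocyte/macrophage-like, so these ratios do not tell G-MDSCs from other neutrophils. Among 10 suppressive mediators, 3 were over 4-fold higher in the positive sort, 1 in the negative sort and 6 neither (median 0.86, above 91.0% of random lists). Cd274, which encodes PD-L1 (chromosome 19, 29367455 to 29388095), was at 2562 and 262 CPM, 9.76-fold higher in the positive sort (9.55 to 9.98). The 2 arginase genes went opposite ways. Arg2 was 10.5-fold higher in the positive sort, at 802 CPM. Arg1 (chromosome 10, 24915221 to 24927484) was 9.18-fold higher in the negative sort (8.98 to 9.38), at 815 against 88.8 CPM. Most Arg1 of the positive sort lay in its 125 monocyte/macrophage-like cells, at 3322 CPM (10794 UMIs). Its neutrophil-like cells had 6.21 CPM (231 UMIs) when I-A/I-E-high and 3.24 CPM (280 UMIs) when I-A/I-E-low. The 88.8 CPM and the 9.18-fold are thus values of the whole sort and not of granulocytes. Slpi and Ptgs2 stood at 4789 and 1447 CPM in the positive sort and at 1314 and 476 CPM in the negative sort. Apoptosis genes of neutrophils had a median of 1.71, with Fas (8.74-fold), Bcl2l11 (5.57-fold) and 1 further gene of 10 over 4-fold higher in the positive sort and none in the negative sort.

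RNA of energy metabolism genes differed between the sorts mainly in the oxidative phosphorylation list, which holds nuclear genes. Of 18 oxidative phosphorylation genes, 10 were over 4-fold higher in the negative sort and 8 neither (median −2.24, with none of 10000 random lists lower). Cox6c was 6.02-fold higher there. None of 17 glycolysis genes reached the 4-fold bound (median 0.79, above 86.8% of random lists). Gapdh stood at 1905 and 1719 CPM and Tpi1 at 817 and 426 CPM. Of 13 hypoxia response genes, 1 passed, Egln3, which encodes an oxygen-sensing hydroxylase, at 4.17-fold higher in the positive sort (4.04 to 4.32). Ero1l and Hilpda were at 961 and 570 CPM against 271 and 163 CPM, and the list's median was 1.29. Iron-handling genes had a median of 1.57, with 2 of 8 over 4-fold higher in the positive sort and 6 neither. Fth1 was at 54880 and 21400 CPM and Ftl1 at 12932 and 4507 CPM. Dissociation and stress genes had a median of 0.997, with 2 of 13 over 4-fold higher in the positive sort, among them Dusp1 (10.7-fold), and 11 neither, so handling of the cells is not excluded as a part of their RNA.

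Genes of monocytes, macrophages and antigen presentation were higher in the negative sort. Of 10 class II presentation genes, 8 were over 4-fold higher there (median −4.10, with none of 10000 random lists lower). H2-Ab1 (chromosome 17, 34257689 to 34269419) was at 38.4 and 678 CPM, 17.7-fold higher in the negative sort, Cd74 18.7-fold, H2-Aa 15.99-fold, H2-Eb1 16.6-fold, H2-DMa 19.3-fold and H2-DMb1 55.6-fold. Ciita, the class II transactivator, was 78.3-fold higher, while H2-DMb2 was at 0.259 and 2.24 CPM, under the floor. Of 11 monocyte and macrophage transcription factors, 6 were higher in the negative sort and 5 neither (median −2.87), with Irf8 45.8-fold and Tcf4 13.4-fold higher. Complement genes had a median of −3.95, with 6 of 10 higher in the negative sort, such as C3ar1 (17.2-fold), and 1 in the positive sort, the C5a receptor gene C5ar1 (6.45-fold). Extracellular matrix and repair genes had a median of −3.005, with 6 of 11 higher in the negative sort, such as Fn1 (36.6-fold) and Tgfbi (10.4-fold), and 1 in the positive sort. Of 16 lysosome and phagocytosis genes, 4 were higher in the negative sort, including Ctss (5.36-fold), and 12 neither (median 0.27). All 7 NADPH oxidase genes were neither (median 0.03), with Cybb at 235 and 946 CPM. Of 5 osteoclast genes, Mmp14 (8.03-fold) and 1 other were higher in the negative sort, and Atp6v0d2, a subunit of the vacuolar proton pump, was 18.9-fold higher in the positive sort (median −0.59).

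**Figure D3:**
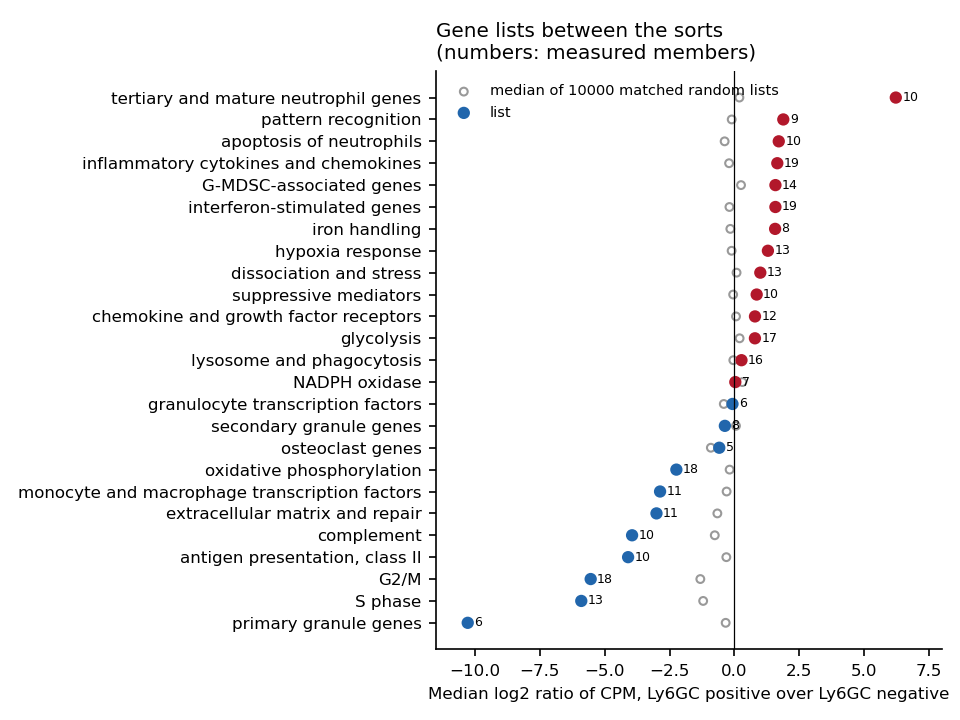
Median log2 ratio of CPM, Ly6GC positive over Ly6GC negative, for 25 gene lists (filled points, numbers give the members measured) and the median over 10000 random lists matched on expression (open points). Tertiary and mature neutrophil genes lie at 6.22 and primary granule genes at −10.28.

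Proliferation was nearly confined to the negative sort. All 18 G2/M genes were over 4-fold higher there (median −5.54), with Top2a (chromosome 11, 98992943 to 99024189) 57.1-fold and Mki67 (chromosome 7, 135689784 to 135716361) 18.3-fold higher. Of 13 S-phase genes, 11 were higher in the negative sort and 2 were neither (median −5.90), and Dut was 370-fold higher. At 1000 UMIs per cell, 12 of 13334 cells in the positive sort (0.0900%, 0.0465 to 0.157) and 181 of 1408 cells in the negative sort (12.9%, 11.2 to 14.7) had at least 2 G2/M transcripts. Most were precursors. Of the neutrophil precursor-like cells in the negative sort, 161 of 214 (75.2%, 68.9 to 80.9) met this rule, against 18 of 1083 monocyte/macrophage-like cells (1.66%, 0.988 to 2.61). In the positive sort, all 8 precursor-like cells and 4 of 13205 neutrophil-like cells did. The clusters were drawn from the same RNA, and Top2a and Ccna2 were among the leading genes of a precursor-like cluster with 123 negative-sort cells. Clustering may thus have drawn cycling cells into that class, so these shares describe the classes and test nothing. Thinning left out 203 shallower cells of the positive sort and 32 of the negative sort. Without thinning the shares were 1.28% and 24.4%. Free RNA in droplets remains open for the low share among neutrophil-like cells.

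The surface tags asked whether granulocytes at the implant carried macrophage proteins. Neutrophil-like cells of the positive sort carried a median of 29 F4/80 tag UMIs (quartiles 19 and 47) and 28 I-A/I-E tag UMIs (17 and 51). The cluster of 693 cells with very high UMIs and mostly the highest doublet scores had medians of 79 and 86. Those of the other neutrophil-like clusters ran from 15 to 35 and from 12 to 36. Possible doublets of that cluster remain in the main tag shares and comparisons. The 125 monocyte/macrophage-like cells of the same sort carried 136 and 230. In the negative sort, monocyte/macrophage-like cells carried a median of 68 F4/80 and 36 I-A/I-E tag UMIs, and the I-A/I-E quartiles spanned 11 to 216.5. Neutrophil precursor-like cells there had medians of 23 and 3, and T/NK cell-like cells 3 and 6. The 3 precursor-like clusters were unlike in F4/80, with medians over both sorts of 50 (led by Top2a), 13 (led by Elane) and 2 (led by Hist1h4f). The last was shallow, with a median of 1460 RNA UMIs. Plasmacytoid dendritic cell-like cells had 2 F4/80 and 54 I-A/I-E tag UMIs.

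A mixture of 2 components, with a fixed rule at its means, gave thresholds of 21 F4/80 and 61 I-A/I-E tag UMIs. The F4/80 threshold is the first count above the lower mean (20.3), below which no cell was called high. The I-A/I-E threshold is the first count above the higher mean (60.0), above which every cell was. Neither is the point where the 2 components are equally likely. By these thresholds, 70.1% of the positive sort (69.3 to 70.9) and 73.8% of the negative sort (71.5 to 76.1) were F4/80-high. The I-A/I-E-high shares were 20.6% (19.9 to 21.3) and 31.5% (29.1 to 34.0). The groups are ranges of a continuous tag level and not cell types: 26.4% of positive-sort cells lay within 0.1 log10 units of the F4/80 threshold and 12.3% within 0.1 of the I-A/I-E threshold. Fitted within the positive sort alone, the F4/80-high share was 20.2%. With tag UMIs divided by RNA UMIs the order of the sorts turned for both tags: 86.5% of the positive and 63.2% of the negative sort were F4/80-high, and 68.5% and 37.2% were I-A/I-E-high. The tag shares therefore give no direction between the sorts. No isotype control tag was used here.

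**Figure D4:**
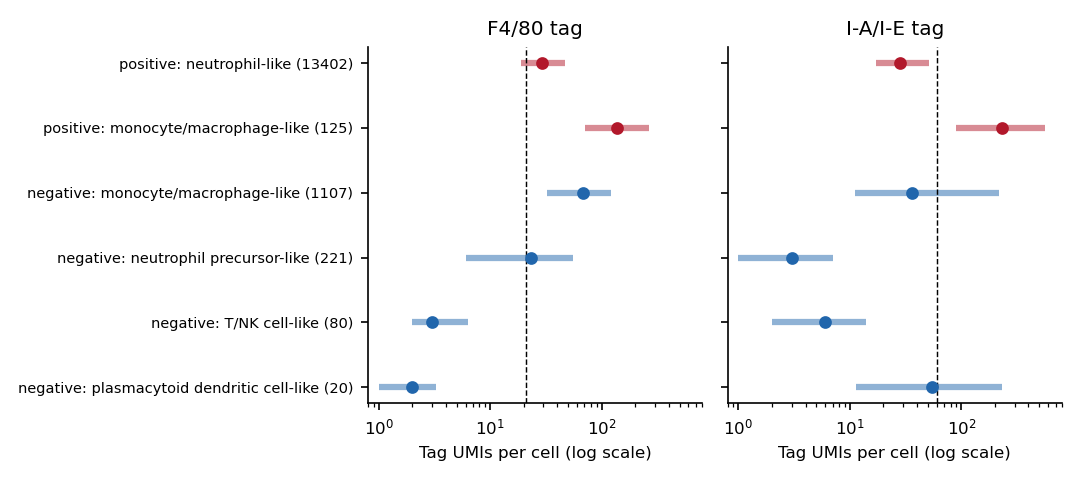
Tag UMIs per cell (log scale) for F4/80 (left) and I-A/I-E (right) by sort and cell class, with cells in brackets; points are medians, thick lines span the quartiles, and the dashed line is the threshold of 21 or 61 tag UMIs. The F4/80 threshold runs through the neutrophil-like range, whose median is 29.

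Tags correlated with the RNA of their genes more in monocyte/macrophage-like cells than in neutrophil-like cells, where that RNA was also seen less often. At least 1 UMI of Adgre1 and of class II RNA was found in 31.4% and 14.7% of neutrophil-like cells, at a median of 7668.5 UMIs, and in 65.1% and 61.6% of the negative sort's monocyte/macrophage-like cells, at 19012 UMIs. Zeros and low depth reduce rho, so the values of the 2 classes are not on equal terms. Across the 1107 monocyte/macrophage-like cells of the negative sort, Spearman's rho was 0.498 between the F4/80 tag and Adgre1 RNA and 0.686 between the I-A/I-E tag and class II RNA. Among the 125 such cells of the positive sort the values were 0.620 and 0.763. Across 13402 neutrophil-like cells rho was 0.189 for F4/80 and 0.151 for I-A/I-E. In those cells the 2 tags correlated with each other at 0.755. Over all cells, F4/80 tag and RNA had rho 0.195 in the positive sort and 0.577 in the negative sort, and I-A/I-E 0.172 and 0.659. With the centred log ratio of the 2 tags the positive sort's values were 0.00811 and 0.0597, and the negative sort's 0.325 and 0.581. Adgre1 RNA itself was at close levels in neutrophil-like cells (130 CPM, 128 to 132) and in monocyte/macrophage-like cells of the positive sort (129 CPM, 117 to 142). Among T/NK cell-like cells of the negative sort, a type that does not transcribe the gene, Adgre1 summed to 11.4 CPM (6.07 to 19.5), a level that free RNA can leave. Cells are not replicates, and no p-value is given for these correlations.

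Within the positive sort, cells with much F4/80 tag were set against cells with little, to find RNA that went with the surface protein. Secondary granule RNA was higher in F4/80-low cells, and 1 small cluster carried this difference. Of 8 secondary granule genes, 6 were over 2-fold higher in the 4048 F4/80-low cells and none in the 9489 F4/80-high cells (median log2 ratio −2.44, high over low). Ngp (chromosome 9, 110419747 to 110423012) was at 3048 CPM in low and 477 CPM in high cells, 6.39-fold higher, and Cd177, Adpgk, Camp, Ltf and Chil3 were between 5.41-fold and 6.39-fold higher. The 4 hemoglobin genes also led this side, from 5 erythroid barcodes that were all F4/80-low. In all, 112 genes passed in favour of low and 29 in favour of high cells. High cells were deeper, with a median of 8122 UMIs against 6869, and after thinning to 1000 UMIs the counts were 27 and 7. Between the extremes of the tag range they were 169 and 70. F4/80-high cells had more Arg1 (114 against 3.30 CPM, 34.6-fold), Pid1 (10.7-fold), Saa3 (2.58-fold) and Cd74 (2.202-fold). The monocyte/macrophage-like cells set this side, since 117 of the 125 were F4/80-high. With neutrophil-like cells only, 6 genes remained higher in F4/80-high cells and Arg1 stood at 4.57 and 2.71 CPM. The low side held, with 119 genes, of which 107 were shared, and again 6 of 8 secondary granule genes (median −2.36).

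The cluster led by Ltf (271 cells, 2.002% of the sort) held 39.2% of the sort's secondary granule UMIs, from 87.5% of Ngp and 84.3% of Camp to 13.2% of Hp and 11.3% of Lcn2, and 194 of its cells were F4/80-low. An alternative chosen after seeing the data left this cluster out of the neutrophil-like cells. None of 6 measured secondary granule genes then passed (median −0.34), Ngp stood at 49.2 CPM in F4/80-high and 72.9 CPM in F4/80-low cells, and the list summed to 4610 and 3877 CPM. Lcn2 set the direction of that sum (4091 and 3136 CPM). Of the 6 genes 2 were higher in F4/80-high cells, and Mmp8 stood at 68.7 CPM in high and 134 CPM in low cells. Genes that passed numbered 15 in favour of low and 9 in favour of high cells. The granule difference thus came largely from these 271 cells.

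The I-A/I-E tag gave a like picture, with the same small cluster behind it. The 2789 I-A/I-E-high cells had more Arg1 (261 against 9.57 CPM, 27.2-fold), Pid1 (13.6-fold), Apoe (6.19-fold), F13a1 (6.14-fold), Cd74 (4.95-fold), Saa3 (2.23-fold) and Pdpn (2.10-fold). Of 6 measured class II presentation genes, 4 were over 2-fold higher in I-A/I-E-high cells and 2 neither (median 2.33). The 10748 I-A/I-E-low cells had more Camp (5.36-fold), Ngp (5.24-fold), Chil3 (4.12-fold), Ltf (4.03-fold), Retnlg (3.26-fold), Ipcef1, Ifitm6 and Anxa1, and 6 of 8 secondary granule genes were higher there (median −2.03). Of the Ltf cluster's 271 cells 258 were I-A/I-E-low, and without that cluster none of 6 measured secondary granule genes passed among neutrophil-like cells (median −0.38). Hba-a1 and Hbb-bs again came from the erythroid barcodes. Totals were 65 genes in favour of high and 51 in favour of low cells, 35 and 17 after thinning, and 8 and 10 among neutrophil-like cells without the Ltf cluster. Other choices raised the counts: 228 genes favoured low cells between the extremes of the tag range, and 101 favoured high cells without the highest doublet scores. Of the monocyte/macrophage-like cells 105 were I-A/I-E-high. Among neutrophil-like cells only, 6 genes were higher in high and 51 in low cells, none of 4 measured class II genes passed (median 0.16), and Cd74 stood at 49.5 and 39.7 CPM.

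Hypoxia and glycolysis genes were then compared across the classes of the positive sort. Neutrophil-like and monocyte/macrophage-like cells carried near-equal sums of hypoxia RNA, at 4263 CPM (4251 to 4274) and 4203 CPM (4133 to 4275) summed over the list, a ratio of 1.01 (0.997 to 1.03). Members went both ways beneath the sum. Ero1l was at 976 CPM in neutrophil-like and 529 CPM in monocyte/macrophage-like cells, but Hif1a at 351 and 736 CPM and Ndrg1 at 81.7 and 203 CPM, and 2 of 13 members were over 2-fold higher in monocyte/macrophage-like cells. Without the most abundant member of the list the ratio was 0.895. Summed glycolysis RNA was lower in neutrophil-like cells, at 10099 CPM (10081 to 10117) against 12631 CPM (12509 to 12753), a ratio of 0.7996 (0.792 to 0.807). Its members went both ways too: 8 of 17 stood higher in neutrophil-like cells, and the median log2 ratio was −0.17. Beyond 2-fold, 1 was higher in neutrophil-like cells, 2 were higher in monocyte/macrophage-like cells and 14 were neither. Hk2 stood at 465 CPM in neutrophil-like and 271 CPM in monocyte/macrophage-like cells, but Gapdh at 1882 and 2905 CPM. The 8 precursor-like cells had 615 CPM of hypoxia and 4275 CPM of glycolysis RNA.

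Among neutrophil-like clusters the spread was wider than between the classes. Hypoxia RNA ran from 722 CPM in the cluster led by Ltf, Itgb2l and Ngp (271 cells) and 1105 CPM in the cluster led by Cd101 and Scrg1 (353 cells) to 6528 CPM in a cluster led by Muc3 and heat shock genes (760 cells). Glycolysis RNA ran from 4162 CPM in the Cd101 cluster to 13756 CPM in a cluster led by stefin genes (375 cells). Hypoxia and inflammatory RNA were both lowest in the Ltf cluster, where secondary granule RNA reached 68703 CPM and cytokine and chemokine RNA 3086 CPM. Cytokine and chemokine RNA was highest in the cluster led by F3, Tagap and Gbp5, at 71603 CPM. The clusters were drawn from the same RNA, so these levels describe them and test nothing.

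**Figure D5:**
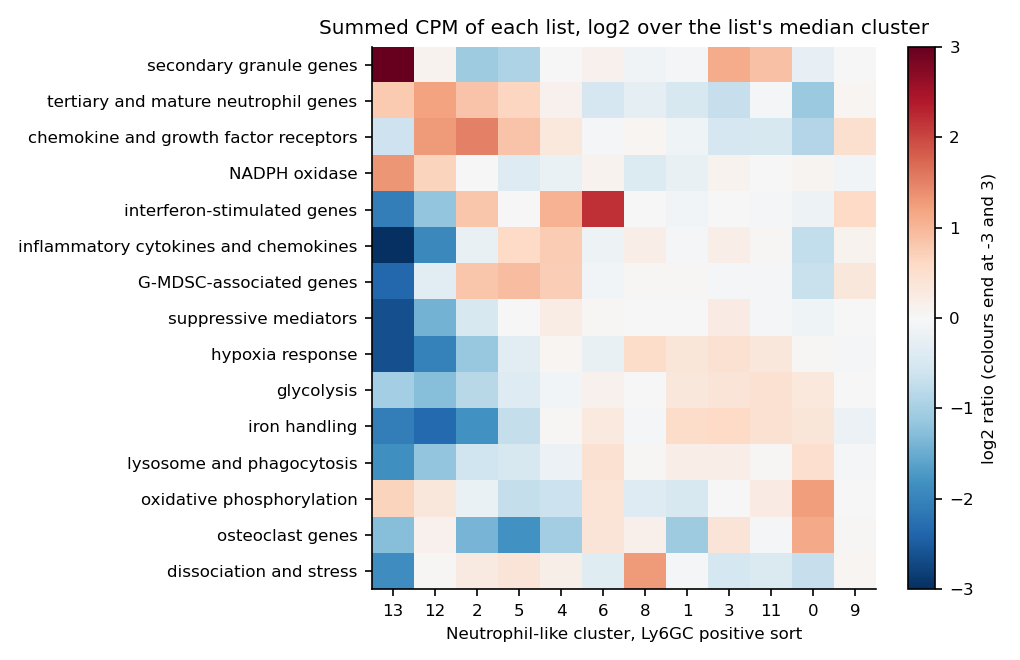
Summed CPM of 15 gene lists in the 12 neutrophil-like clusters of the Ly6GC positive sort, as log2 over the list's median cluster (colours end at −3 and 3). Clusters 13 (led by Ltf) and 12 (led by Cd101) have the least hypoxia RNA, at 722 and 1105 CPM, and cluster 6 the most interferon-stimulated RNA, at 24255 CPM.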

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

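Of the tests below, those of neutrophil and macrophage doublets, both of random carry-over across the gate and that of depth as the cause of the correlation of the 2 tags were chosen only after the result was seen.

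Hemoglobin RNA stood out in barcodes that the comparisons do not use. The 90 barcodes of the Ly6GC positive sort left out by the cell filter held 73544 CPM of hemoglobin RNA (14528 of 197542 UMIs), above the 15.2 CPM that a count of 0 allows, and 6 of them were erythroid. Among used cells the level was 318 CPM, nearly all in 5 erythroid barcodes. The source of this RNA was not tested, and no biological explanation was tested.

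As doublets of a neutrophil and a macrophage, the 125 monocyte/macrophage-like cells behind the Ly6G gate, the first pattern weighed, would carry a neutrophil RNA share of 33.4%; the median was 2.84%, and 14.4% of them (18 cells, 8.76 to 21.8) reached 0.5 of that share, which argues against doublets for most and leaves 18 open; their median depth of 26598 UMIs, against 19012 in the negative sort's class, is what added neutrophil RNA would also give, but the RNA itself was not there in most. As random carry-over they would have the make-up of the negative sort's class, where 37.7% (34.8 to 40.6) lay in the Ccr2-rich cluster; here 16% did (10.1 to 23.6), which decides nothing, since these intervals leave out differences between 2 single libraries. For the 105 cells in the Arg1-rich cluster, 8 of 128 macrophage genes lay beyond 4-fold from the same cluster of the negative sort. Of these 7 were lower, such as Ccr2 and Plac8, and Mmp12 was higher (4.31-fold, 4.09 to 4.53). In 1000 random draws of that cluster's cells at most 2 genes did so. The draws came from the negative sort alone, so they too leave out differences between the 2 libraries and decide nothing. Random carry-over stays open for these 105 and the 20 other cells, as does a gate error tied to cell state. A graded passage from neutrophil-like to macrophage-like RNA would leave intermediates. A macrophage RNA share of 20% to 80% was found in 71 cells (55.5 to 89.6), a number between the bounds set in advance. Of these 62 were already in this class and 6 were neutrophil-like. The gene set took only genes at least 20-fold higher in the negative sort's class than in neutrophil-like cells. Genes with much RNA in neutrophil-like cells were thus left out, and the low number of neutrophil-like intermediates was partly set by this choice. A passage cannot be told apart from macrophages with less RNA of this gene set.

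The second pattern is the neutrophil-like cluster of very high UMIs (693 cells). Doublets of 2 neutrophil-like cells would average the other clusters and lead in hardly any gene. Of 2426 genes, 2 exceeded every other neutrophil-like cluster (Eldr, 1.12-fold, and Mirt1, 1.10-fold), against a median of 189 (16 to 955) in the other clusters, which fits doublets of 2 neutrophil-like cells. Large cells with an average profile stay open, and no biological explanation was tested.

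The third pattern is the tag signal on neutrophil-like cells. Binding without the antigen as the whole cause would leave no link between tag and RNA once depth and the other tag are taken out: the partial rank correlation was 0.0774 for F4/80 (0.189 before) and 0.0694 for I-A/I-E (0.151 before). Both lie between the bounds set in advance, so binding with and without antigen cannot be told apart. RNA depth as the whole cause of the correlation of the 2 tags would remove it once total RNA UMIs are taken out. The correlation was 0.728 given total UMIs and 0.755 without, which argues against RNA depth alone. Total RNA UMIs followed the tags only in part (rho 0.351 for F4/80 and 0.291 for I-A/I-E). Tag capture and cell size were not measured, so both stay open. Shared unspecific binding and a joint change of both proteins stay open too.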

How the results depend on the processing

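Results were rerun under the alternatives; 118 main values held and 48 moved, and of the list medians 186 held and 9 moved; no called value changed sign, but the order of the sorts turned for both tag shares with tag UMIs divided by RNA UMIs, and the secondary granule median went from −0.37 to 2.97 with neutrophil-like against monocyte/macrophage-like cells. The cause was not tested. No paired analysis was possible because each sort had 1 RNA library. Genes over 4-fold apart numbered 241 and 470 (positive and negative sort; main 436 and 1718) at a floor of 100 CPM, where 33.9% favoured the positive sort (main 20.2%), and 2935 favoured the negative sort at 5 CPM. Of 123 named genes none reversed, but the call changed for 20 with neutrophil-like against monocyte/macrophage-like cells, for 6 thinned, and for 5 each with median-of-ratios scaling, the denominator without the 20 most abundant genes and the floor of 100 CPM. Without a cell filter, neutrophil-like cells were 98.5% of the positive sort and monocyte/macrophage-like cells 71.4% of the negative sort; the latter were 72.9% with 4000 variable genes. F4/80-high shares in the positive sort were 1.17% (99th percentile of neutrophil-like cells), 86.5% (tag UMIs divided by RNA UMIs), 73.6% (stricter filter), 20.2% (mixture within each sort) and 64.9% (without the highest doublet scores), and in the negative sort 2.43%, 63.2% and 81.2% (percentile, divided, within each sort). I-A/I-E-high shares in the positive sort were 1.29%, 68.5%, 19.4%, 19.7% and 19.01% in the same order of 5 settings, and 14.9%, 37.2% and 21.5% in the negative sort in the order of 3. With the centred log ratio, rho of F4/80 with its RNA was 0.00811 and 0.325 in the positive and negative sorts and of I-A/I-E 0.0597 and 0.581. Genes higher in F4/80-high cells (main 29) numbered 6 in neutrophil-like cells only, 70 between the extremes of the tag range and 7 thinned, and in F4/80-low cells (main 112) 169 between extremes and 27 thinned. For I-A/I-E-high (main 65) they were 6 in neutrophil-like cells only, 35 thinned and 101 without the highest doublet scores, and for I-A/I-E-low (main 51) 228 between extremes and 17 thinned. In neutrophil-like cells without the cluster richest in secondary granule RNA, 9 genes were higher in F4/80-high and 15 in F4/80-low cells, and 8 in I-A/I-E-high and 10 in I-A/I-E-low cells. Cycling cells were 1.28% of the positive sort unthinned, and 9.73% (at least 3 transcripts), 24.4% (unthinned) and 14.7% (2000 UMIs) of the negative sort. The ratio of neutrophil-like to monocyte/macrophage-like cells for hypoxia RNA was 0.895 without the most abundant member and 1.11 with a denominator without the 20 most abundant genes, and for glycolysis RNA 0.845 and 0.876.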

Other observations

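The monocyte/macrophage-like cells of the negative sort formed 2 groups. In 690 cells Arg1 reached 2029 CPM and Nos2 1312 CPM, with Spp1 at 1960 CPM and Cd274 at 632 CPM; in the other 417 cells these stood at 9.86, 3.66, 42.2 and 12.3 CPM. Arginase 1 and inducible nitric oxide synthase use the same amino acid and are often read as markers of opposed macrophage states. Here both RNAs were high in sums over the same group of cells, and whether single cells held both was not counted. The smaller group had more Ccr2 (1691 against 512 CPM), Cx3cr1 (315 against 42.5 CPM), Ace (35.6 against 3.84 CPM) and Nr4a1 (115 against 21.9 CPM), genes of blood monocytes. Groups were drawn from the same RNA, so these values describe them.

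The 125 cells of this class behind the Ly6G gate had less RNA of some monocyte genes than the class in the negative sort. Ccr2 stood at 65.2 against 969 CPM, Ly6c2 at 110 against 769 CPM and Plac8 at 237 against 2069 CPM. Cx3cr1 was also lower (28.3 against 148 CPM). Other monocyte genes were closer, with Fn1 at 1015 against 1281 CPM, F13a1 at 1248 against 1553 CPM and Csf1r at 383 against 429 CPM. Nr4a1 stood at 47.1 against 58.2 CPM and Ace at 17.8 against 16.2 CPM. The 125 cells had more Spp1 (5235 against 1216 CPM), Mmp12 (949 against 142 CPM) and Arg1 (3322 against 1246 CPM). Other macrophage genes went both ways: Apoe was higher (1693 against 1075 CPM), C1qb near equal (163 against 160 CPM) and C1qa lower (53.9 against 102 CPM). Part of these differences lies in the mix of the 2 groups. Within the Arg1-rich group alone Spp1 was 2.79-fold, Mmp12 4.31-fold and Arg1 1.70-fold higher. There Ly6c2 was 5.16-fold and C1qa 2.68-fold lower. Ly6g had 5 UMIs in them and 0 in the other sort's class. Other neutrophil RNA moved with it, such as S100a8 (2765 against 703 CPM), S100a9 (2160 against 379 CPM) and Retnlg (60.9 against 0.735 CPM), so these Ly6g UMIs do not show that the cells transcribe the gene. The T/NK cell-like cells of the negative sort carried Ly6c2 at 1106 CPM, and the plasmacytoid dendritic cell-like cells at 1439 CPM, so the Ly6C gate alone takes in both.

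Hypothesis 1: some macrophages at the implant may carry surface Ly6G because they arose from granulocytes, or because they took up neutrophils and hold their membrane. Doublets do not account for most of them (14.4% reached 0.5 of the share of a doublet). Random carry-over stays open for the 105 cells in the Arg1-rich cluster and the 20 others (16% of the class), as does a gate error tied to cell state. In the Arg1-rich cluster 8 of 128 macrophage genes lay beyond 4-fold, but the draws used there leave out differences between libraries. A passage stays open too: of 71 cells with a middle macrophage RNA share, 62 belonged to this class and 6 were neutrophil-like. The gene set behind that share was chosen as low in neutrophil-like cells, so this split was partly set by the choice. A test is to label granulocytes by a Ly6g-driven recombinase and look for label in the DNA of sorted macrophages, where engulfed neutrophils would not leave a recombined macrophage genome. The granulocyte origin fails if macrophages behind the gate have no recombined allele.

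Hypothesis 2: the 271 cells of the Ltf cluster may be recent arrivals, since they held secondary granule RNA, which neutrophils lose after leaving the marrow. Of them 194 were F4/80-low and 258 I-A/I-E-low. Tag-low neutrophils at large give no such basis: without this cluster 15 genes were higher in F4/80-low cells, against 119 with it, and no secondary granule gene was among them. The cluster was picked as the richest in this RNA, so the loss of these genes was partly set by the choice. An injected nucleotide label that marks each wave of new neutrophils would test the hypothesis: label should appear in cells with Ltf RNA before it appears in the others. Isotype tags and animals without Adgre1 would tell antigen from unspecific binding, which the partial correlations of 0.0774 and 0.0694 leave open.

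Hypothesis 3: neutrophils may turn on hypoxia genes as they move toward the implant. The cluster richest in secondary granule RNA had 722 CPM of hypoxia RNA and the highest cluster 6528 CPM, while the sums of the 2 classes of the positive sort were near equal (ratio 0.895 without the most abundant member). A hypoxia probe given before tissue collection, read with Ltf and Muc3 in sections, would test it. The idea fails if probe binding and hypoxia RNA are unrelated or do not rise near the implant. Handling remains an alternative, since the cluster with most hypoxia RNA also had most stress RNA, at 21299 CPM.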
